A study of Mus musculus with 2 samples.

How the data were processed

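Droplet single-cell RNA sequencing was used to profile dendritic cells (DCs) sorted as CD3-B220-CD11c+MHC-II+ cells from the mesenteric lymph nodes (mLN) and the small-intestinal lamina propria (siLP) of 15-day-old mice carrying a reporter at Gm38411, with the iCre recombinase and human CD2 (hCD2). Libraries were made with the Chromium 3' v3 chemistry, per the labels' protocols, as 1 gene expression library and 1 hashtag library from the same droplets. Cells of 6 biological replicates, 3 per tissue, were pooled after each had been marked with its own hashtag antibody (hashtags 2, 4, 5, 6, 8 and 9), per the labels. The labels do not say which hashtag marks which tissue. The tissues were therefore not compared, no hashtag was given a tissue from its values, and each hashtag served as 1 replicate within which cell classes were contrasted.

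The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and per hashtag antibody in each barcode, made with Cell Ranger 8.0.1 on the mm10 build, per the submitters' processing notes. Whether introns were counted and whether counting used strand was not given in the sources used here. Per the file headers, the matrix held 32289 gene features, among them the added sequences iCre, Cre, hCD2 and tdTomato, and 6 hashtag features. It held 3247803 barcodes, of which 27679 were in the deposited assignment table, and these carried 88.8% of the 310491000 gene UMIs. The deposited assignment table gave each barcode a hashtag call and a probability as a fraction between 0 and 1. Of its 18 columns, 15 were not used. It called 4815 barcodes multiplets, 1706 blank and 1919 unassigned, and these entered no comparison.

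Of 19239 cells with a single hashtag, 1294 had fewer than 500 genes and 3627 had more than 10% mitochondrial counts, and 15480 passed both filters. Scrublet marked 32 of these as doublets (0.207%, threshold 0.528). A share this low was taken to mean that the caller had missed doublets among these cells, which was not tested. An additional setting therefore removed the 264 cells most of whose 30 nearest neighbours were hashtag multiplets. The 15448 remaining cells were normalised to 10000 UMIs and log-transformed, and 2000 variable genes were reduced to 30 principal components. Genes of the fixed lists, the reporter gene, the added sequences, and mitochondrial and ribosomal protein genes were kept out of this step. A graph of 15 neighbours was clustered by the Leiden method at resolution 1 into 35 clusters. Clusters were named "-like" from markers of 16 cell types fixed before the data were examined. Clusters 13 and 24, chosen after the clusters had been seen, were clustered again on 10 principal components, at resolutions 0.8 and 0.5. The parts of cluster 24 were named apart: 59 cells as ILC3-like and 22 as T or NK cell-like, while 14 stayed unnamed. Of the 35 clusters, 8 stayed unnamed, either because their markers were mixed, because their leading genes went against a name, or because their cells held too few UMIs. Cluster 13, with 339 cells, was kept out of the RORgt+ DC-like class by a requirement that was set after its values were seen. Some genes and the results that need them are not reported here.

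Raw counts were summed per class and hashtag wherever a class held at least 10 cells, which gave 23 summed libraries from RORgt+ DC-like, migratory DC-like, cDC1-like and cDC2-like cells. These were fitted together with edgeR's quasi-likelihood test (TMM scaling, filterByExpr) with class and hashtag as terms, so that each contrast was made within hashtags. All classes of a hashtag came from the same biological replicate, per the labels, which is what pairs the libraries. The fit tested 11973 genes, had 14 residual degrees of freedom and a common dispersion of 0.0544. Counts of called genes were taken over the 10865 tested genes that had entered neither the clustering nor a marker list. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Errors of log2 fold changes are standard errors (SE) from the fit, and pairs are hashtags that held both classes. Hashtag 8 held 3 RORgt+ DC-like cells, too few for a summed library, so each contrast rests on 5 pairs.

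Gene lists, markers, the tests of the contrasts, the first set of alternative settings and the rule for named genes were fixed before the data were examined. Further settings and tests were added after the data had been seen and are named as such where they are given. There were 14 lists with 219 genes, of which 217 had a feature; 1 list held only the reporter gene. Lists were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. The rule named the reporter gene and transgenes, then 11 chosen genes whatever their result. It added from each list at most 3 called members with the largest fold changes and the same sign in all pairs. Last, it took the 5 highest and 5 lowest fold changes among the other called genes that reached 10 CPM and had the same sign in all pairs. Where a class held no UMI of a gene, a bound was computed against 3 counts over the class. With 1 to 3 counts, the ratio of UMI shares over the class is given with its exact 95% interval. Shares of cells carry Wilson 95% intervals, a share of 0 carries the limit set by 3 counts, and intervals and bounds cover counting error only. To compare classes of unequal depth, each cell was thinned to 2000 UMIs and shallower cells were left out.

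The fits were tested on simulated data with 11799 genes, 100 of them changed by each fold size. Against migratory DC-like cells 54 of the 2-fold and 94 of the 4-fold changes were recovered, against cDC2-like cells 57 and 99, and against cDC1-like cells 56 and 100. Unchanged genes made up 6.21%, 4.79% and 2.44% of the simulated calls. Every gene was drawn with the common dispersion, and the classes of a hashtag shared the same mean profile apart from the planted changes. These rates therefore do not give the error rate of the real calls, where spread and class differences vary by gene and hashtag. Alternatives covered DESeq2, other size factors, no low-count filter, at least 30 cells, no hashtag block, each hashtag left out, equal UMI totals, other cell filters, other resolutions and stricter hashtag calls. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.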

Results

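The series asks about RORgt+ DCs, a rare DC type, in young mice. Gene counts were obtained for 15448 cells of 6 replicates, each marked by a hashtag antibody. Between 1480 and 4853 cells per hashtag were analysed. Hashtags 2, 4 and 5 held 11645476, 12585112 and 15279483 UMIs, with medians of 6568, 6228 and 6552 UMIs per cell. Hashtags 6, 8 and 9 held 40508116, 29974899 and 63446138 UMIs, with medians of 12955, 12000 and 12927 UMIs per cell. The tissue behind each hashtag is not named in the labels, so values are given per hashtag and contrasts were made between cell classes of the same hashtag.

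Most cells were classical DCs, as the CD11c+MHC-II+ gate sets. Across the 6 hashtags, cDC2-like cells made up 34.6% to 58.5% of cells (median 47.1%, 7828 cells), and cDC1-like cells 9.04% to 19.9% (median 17.4%, 2197 cells). Migratory DC-like cells, which express Ccr7 and Fscn1, ranged from 0.629% to 25.9% (median 12.3%, 1326 cells). RORgt+ DC-like cells, named from markers that include Prdm16, Col17a1, Ccr6 and Pigr, were rare at 0.118% to 2.16% (median 1.23%, 146 cells). They made up 2.16%, 1.92% and 1.71% of cells in hashtags 2, 4 and 5, and 0.745%, 0.118% and 0.515% in hashtags 6, 8 and 9. Outside these classes the gate had let through 375 macrophage-like, 328 T or NK cell-like and 59 ILC3-like cells, the last being innate lymphocytes. Another 2837 cells stayed unnamed (18.4% of all, 0.608% to 27.6% per hashtag). Most were of cluster 1, with 2002 cells and Ccr7 among its leading genes, which held 632, 455 and 909 cells of hashtags 6, 8 and 9. The cDC2-like and migratory DC-like shares are given without it. Cluster 13, kept out of the RORgt+ class by a requirement set after its values were seen, held 7.16%, 5.19%, 7.66%, 0.162%, 0.0393% and 0% of cells in hashtags 2, 4, 5, 6, 8 and 9. The 0 of 4853 cells in hashtag 9 allows a share of up to 0.0618%.

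The RORgt+ DC-like class joined a pair of clusters, and different ones held most of it in different hashtags. The one numbered 26, with Prdm16 and Col17a1 among its leading genes, held 21 of 23 cells in hashtag 6 and 24 of 25 in hashtag 9. The one numbered 28, led by Prdm16, Cep112 and Col17a1 and with Aire among its 10 leading genes, held 22 of 32, 20 of 31 and 23 of 32 cells in hashtags 2, 4 and 5. The other classes were split in the same way: most cDC2-like cells lay in clusters 3 and 7 in hashtags 2, 4 and 5 and in clusters 0, 2 and 4 in hashtags 6, 8 and 9. Most cDC1-like cells lay in cluster 5 in the former and in clusters 6 and 9 in the latter. Most migratory DC-like cells lay in clusters 8, 14 and 17 in the former and in cluster 23 in the latter. Each contrast below was therefore also run on single clusters and on part of the hashtags.

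**Figure D1:**
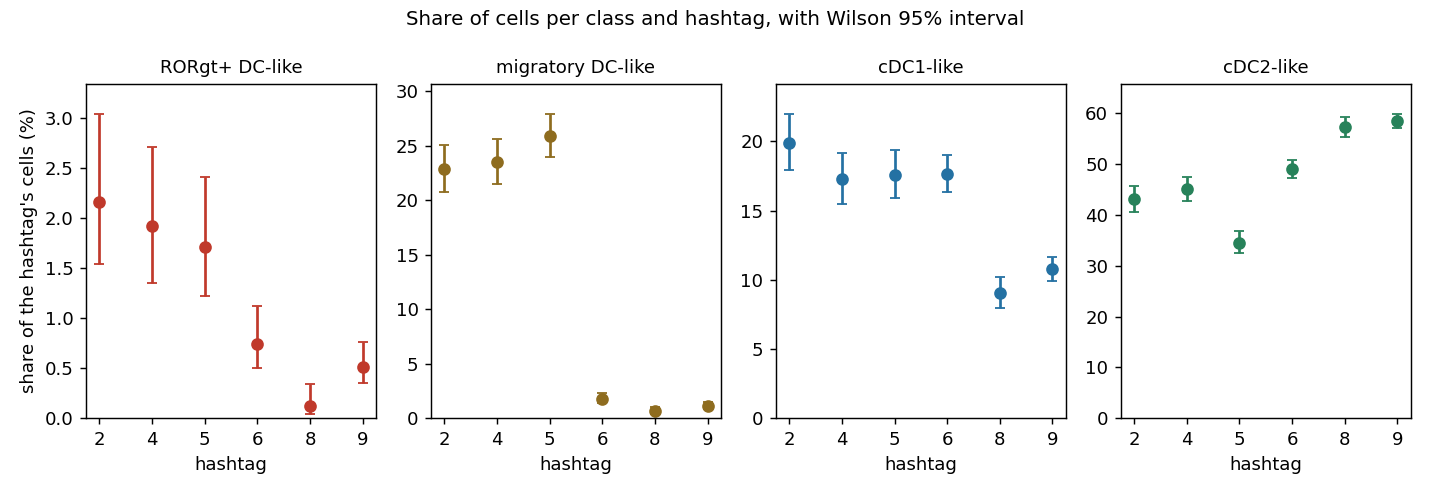
Percent of analysed cells in each named class (y axis, percent) for hashtags 2, 4, 5, 6, 8 and 9 (points; bars are Wilson 95% intervals). RORgt+ DC-like cells stay between 0.118% and 2.16%, while migratory DC-like cells range from 0.629% to 25.9%.

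The reporter sits at Gm38411, and its counts marked the RORgt+ DC-like class. Whether intronic reads or reads of either strand were counted is not given in the sources used here, so these counts may include reads other than those of its spliced transcript. The gene was kept out of the clustering and of the markers. It had 149 UMIs in the summed RORgt+ DC-like libraries (median 62.4 CPM, range 41.5 to 79.2 CPM over 5 hashtags), 9 in cDC2-like, 1 in migratory DC-like and 0 in cDC1-like libraries. Gm38411 was 691.6-fold higher than in cDC2-like cells (95% counting interval 354.7 to 1542) and 736-fold higher than in migratory DC-like cells (130.1 to 29261). It was at least 798.4-fold higher than in cDC1-like cells, against 3 counts over that class. The fitted log2 fold changes were 9.09 ± 0.48 (SE, edgeR adjusted p = 1.68e-09), 9.02 ± 0.63 (adjusted p = 6.03e-08) and 11.42 ± 0.62 (adjusted p = 1.44e-09), higher in 5 of 5 pairs each. With 9, 1 and 0 UMIs in the other class, their sizes depend on the prior count: without hashtag 4 the value against migratory DC-like cells moved to 11.37. The hCD2 reporter sequence followed with 123 UMIs, 570.9-fold (291.1 to 1278) above cDC2-like, 202.5-fold (67.7 to 995.5) above migratory DC-like and 1977-fold (348.3 to 78722) above cDC1-like cells. The iCre sequence had 10 UMIs, too few to be tested, and was 104.4-fold (30.1 to 456.2) above cDC2-like, at least 16.5-fold above migratory DC-like and at least 53.6-fold above cDC1-like cells, the latter pair against 3 counts.

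Per cell, the reporter was also found in ILC3-like cells. After thinning to 2000 UMIs, Gm38411 was detected in 20 of 144 RORgt+ DC-like cells (13.9%, 9.17% to 20.5%) and 8 of 59 ILC3-like cells (13.6%, 7.03% to 24.5%). It was detected in 3 of 7666 cDC2-like cells (0.039%), 0 of 2180 cDC1-like cells, which allows up to 0.138%, and 0 of 1185 migratory DC-like cells, which allows up to 0.253%. Macrophage-like cells held it in 0 of 366, which allows up to 0.82%. These limits hold for cells with a UMI at this depth, not for cells expressing the gene. Median depths before thinning were 13722.5 UMIs in RORgt+ DC-like, 7096 in ILC3-like, 11362.5 in cDC2-like and 12022 in macrophage-like cells. Unthinned shares of Gm38411 were 47.9% in RORgt+ DC-like, 39.0% in ILC3-like and 0.102% in cDC2-like cells. Thinned to 1000 UMIs, the share was lower in ILC3-like than in RORgt+ DC-like cells. Thinning left out 2 RORgt+ DC-like, 0 ILC3-like, 162 cDC2-like, 17 cDC1-like and 141 migratory DC-like cells as too shallow. hCD2 was detected in 10.4% of RORgt+ DC-like and 11.9% of ILC3-like cells after thinning, against 2 of 7666 cDC2-like cells. Prdm16 set these types apart, at 84.0% of RORgt+ DC-like and 1.69% of ILC3-like cells, against 0.404% of cDC2-like cells. Prdm16 was a naming marker of the RORgt+ class, so this describes the classes only.

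**Figure D2:**
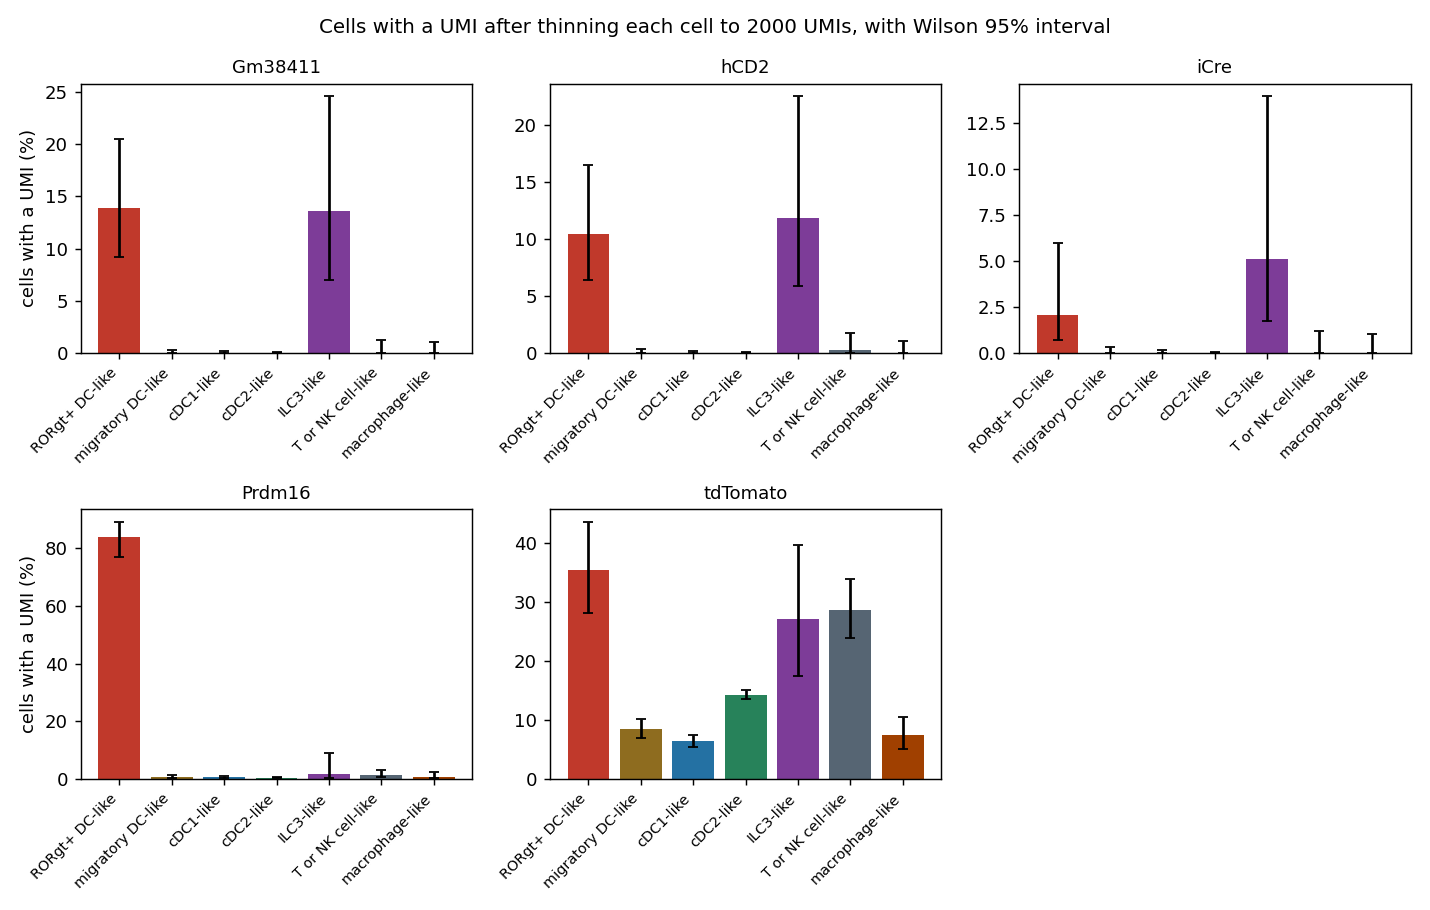
Percent of cells with at least 1 UMI of Gm38411, hCD2, iCre, Prdm16 and tdTomato after thinning each cell to 2000 UMIs (y axis, percent), by cell class, with Wilson 95% intervals. Gm38411 reaches 13.9% of RORgt+ DC-like and 13.6% of ILC3-like cells and 0.039% of cDC2-like cells.

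The added sequence tdTomato, which the genotype label does not name, was less specific. It was higher in RORgt+ DC-like than in migratory DC-like cells (log2 fold change 1.68 ± 0.25, edgeR adjusted p = 3.35e-05), cDC2-like cells (1.63 ± 0.24, adjusted p = 2.18e-05) and cDC1-like cells (2.91 ± 0.25, adjusted p = 1.42e-08), in 5 of 5 pairs each. Without the hashtag block the first pair of calls was lost (adjusted p = 0.0961 and 0.203). After thinning, tdTomato was detected in 35.4% of RORgt+ DC-like, 28.6% of T or NK cell-like, 27.1% of ILC3-like, 14.2% of cDC2-like and 6.42% of cDC1-like cells. These shares pool hashtags with unequal tdTomato levels and class make-up. In hashtags 2, 4 and 5 RORgt+ DC-like cells held tdTomato at 123.9, 121.8 and 145.5 CPM. T or NK cell-like cells there held more, at 181.1, 164.4 and 177.9 CPM. ILC3-like cells held 99.0 and 218.9 CPM in hashtags 4 and 5. In hashtags 6 and 9 RORgt+ DC-like cells reached 448.8 and 509.0 CPM. Barcodes with at most 100 UMIs, which hold mainly free RNA, carried tdTomato at 129.5 CPM and Gm38411 and hCD2 at 0.934 CPM each.

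**Figure D3:**
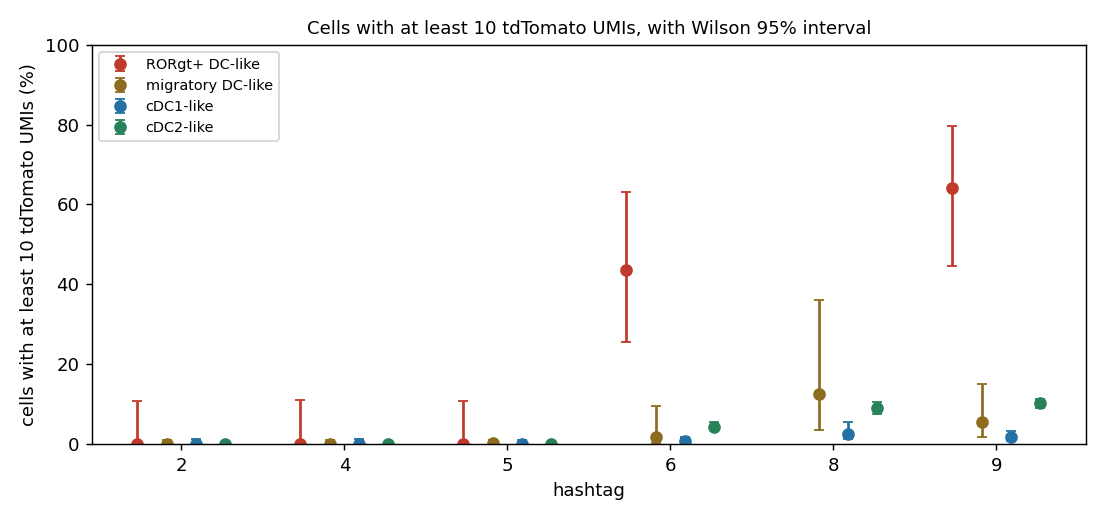
Percent of cells with at least 10 tdTomato UMIs (y axis, percent) by hashtag and DC class, with Wilson 95% intervals. In hashtags 6 and 9 RORgt+ DC-like cells reach 43.5% and 64.0% and cDC2-like cells 4.42% and 10.2%. Counts were not thinned, and the RORgt+ DC-like cells there were deeper, with medians of 23146 and 24564 UMIs against 13064 and 13228 in cDC2-like cells.

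The first contrast asked how RORgt+ DC-like cells differ from migratory DC-like cells, mature DCs named from markers that include Ccr7. The former also held Ccr7: cluster 28 was at 404.3, 683.8 and 557.4 CPM in hashtags 2, 4 and 5. There, migratory DC-like cluster 8 was at 394.3, 435.7 and 463.0 CPM and cluster 14 at 609.4, 560.9 and 634.8 CPM. Cluster 26 was at 129.8, 28.8 and 0 CPM there. In hashtags 6 and 9 it was at 466.4 and 333.3 CPM, against 2538.8 and 2490.5 CPM in migratory DC-like cluster 23. RORgt+ DC-like cells had less of the ligands that act on T cells: 12 of 16 tested costimulatory and coinhibitory ligands fell and 0 rose. Cd274, which encodes PD-L1, fell by the largest fold among the chosen genes (log2 fold change -2.90 ± 0.22), with Cd80 (-2.05 ± 0.27), Cd86 (-1.82 ± 0.36) and Cd40 (-1.81 ± 0.29), the receptor for CD40 ligand; Cd86 did not pass with cluster 28 alone (adjusted p = 0.218). Genes of MHC class I presentation were also lower, with 11 of 13 fallen, among them H2-D1 (-1.47 ± 0.16), the immunoproteasome subunit Psmb10 (-1.44 ± 0.19) and the peptide-trimming enzyme Erap1 (-1.29 ± 0.19), although this list did not pass with an estimated correlation (adjusted p = 0.187). Higher genes included Ltb, which encodes lymphotoxin beta (3.51 ± 0.46), and the scavenger receptor gene Stab1 (4.80 ± 0.42). Each of these genes went the same way in 5 of 5 pairs.

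Of the 10865 genes counted, 3541 passed the edgeR test against migratory DC-like cells, 1828 higher and 1713 lower in RORgt+ DC-like cells (51.6% higher). With relative log expression size factors 59.9% of the calls were higher, with DESeq2 60.1% and with cluster 26 alone 44.7%. DESeq2-type size factors shifted the median of all genes by 0.107 log2 relative to the main scaling. The costimulatory and coinhibitory ligands were lower as a list (camera adjusted p = 3.94e-08, and 0.0322 with an estimated correlation), with 13 of 16 called when adjusted over the list alone. This was the 1 list whose call held with an estimated correlation. MHC class I presentation was lower (adjusted p = 4.72e-05, adjusted p = 0.187 with an estimated correlation, 12 called when adjusted over the list alone). Of 12 chemokines 6 fell and 6 did not pass, with Ccl5 at -5.40 ± 0.50 and Ccl17 at -5.36 ± 0.76 (list adjusted p = 0.00216, adjusted p = 0.186 with an estimated correlation, 9 called when adjusted over the list alone). Of 13 cytokines 8 fell and 1 rose: Il12b, a subunit of IL-12, was at -6.84 ± 0.96, and Il23a at 3.59 ± 0.77 was the 1 that rose, by 2.89, 1.05, 1.16, 7.75 and 4.98 log2 in hashtags 2, 4, 5, 6 and 9 and without a call with cluster 28 alone (adjusted p = 0.189) (list adjusted p = 0.0147, adjusted p = 0.198 with an estimated correlation, 11 called when adjusted over the list alone). Of 10 tolerance-linked enzymes and receptors 5 fell, among them Lilrb4a (-3.71 ± 0.37) and the adenosine receptor gene Adora2a (-3.09 ± 0.30), with 5 called when adjusted over the list alone (list adjusted p = 0.0257, adjusted p = 0.187 with an estimated correlation). Of 15 genes of cholesterol and sterol synthesis 5 fell, with 5 called when adjusted over the list alone (list adjusted p = 0.0475, adjusted p = 0.517 with an estimated correlation). With cluster 28 alone, of these 6 lists only the costimulatory and coinhibitory ligands passed; MHC class I presentation (adjusted p = 0.0686), cytokines (0.0735), chemokines (0.177), cholesterol and sterol synthesis (0.422) and tolerance-linked enzymes and receptors (0.526) did not. Cytokines also did not pass with cluster 26 alone (0.0808) or hashtags 6 and 9 only (0.0711). With hashtags 2, 4 and 5 only, 4 lists passed, and 4 did with hashtags 6 and 9 only. In both settings lists other than cytokines therefore lost their call too.

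The other 7 lists did not pass against migratory DC-like cells. Core dendritic cell identity had 6 of 18 genes lower, 2 higher and 8 called when adjusted over the list alone (adjusted p = 0.0581), and the NF-kB and TNF receptor family had 8 of 19 lower, 1 higher and 9 called when adjusted over the list alone (adjusted p = 0.0581). MHC class II presentation went both ways, with 3 of 15 higher, 4 lower and 8 called when adjusted over the list alone (adjusted p = 0.679). In retinoic acid metabolism and signalling 4 of 13 were higher, 2 lower and 6 called when adjusted over the list alone (adjusted p = 0.327). TGF-beta activation and signalling had 3 of 13 lower and 3 called when adjusted over the list alone (adjusted p = 0.164). Toll-like receptors and adaptors had 4 of 15 lower, 2 higher and 7 called when adjusted over the list alone (adjusted p = 0.117), with Tlr12 at 4.20 ± 0.33 and Ly96 at -3.14 ± 0.44. Phagocytosis and scavenging had 3 of 11 higher, 2 lower and 6 called when adjusted over the list alone (adjusted p = 0.679).

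Among the chosen genes, the DC growth factor receptor gene Flt3 (log2 fold change -2.10 ± 0.16, edgeR adjusted p = 9.49e-09), the DC transcription factor gene Zbtb46 (-0.93 ± 0.14, adjusted p = 4.2e-05) and Tnfrsf11a, which encodes RANK (-1.14 ± 0.28, adjusted p = 0.00405), were lower than in migratory DC-like cells in 5 of 5 pairs. Aldh1a2, which encodes a retinal dehydrogenase, was at -1.44 ± 0.52 (adjusted p = 0.0375, lower in 5 of 5 pairs). Itgav (0.03, adjusted p = 0.957, 2 of 5 pairs higher) and Itgax (0.52 ± 0.23, adjusted p = 0.0945, 4 of 5 pairs higher) did not pass. Itgb8, which encodes a subunit of the TGF-beta-activating integrin, was at -0.01 ± 0.47 over all pairs (adjusted p = 0.993), a mean of pairs that went both ways, and at 1.46 with cluster 28 alone (adjusted p = 0.0350). Its differences were -0.16, 0.48, 0.84, -2.74 and -3.49 log2 in hashtags 2, 4, 5, 6 and 9. Among other genes, Gpr39 was at least 223.9-fold higher and Slamf1 at least 26.9-fold lower, each against 3 counts over the class without a UMI. Ifi209 was 71.2-fold (24.3 to 345.8) and Klrk1 35.5-fold (12.1 to 172.7) lower, from 3 UMIs each. The call for Aldh1a2 was lost without hashtag 4 (adjusted p = 0.1005), 5 (0.0566), 6 (0.122) or 9 (0.0584), and with cluster 28 alone, which also ended the calls for Tnfrsf11a (0.897) and Cd86 (0.218). The tolerance-linked enzymes and receptors lost their call without hashtag 5 (adjusted p = 0.0930), and cholesterol and sterol synthesis without hashtag 5 (0.0794) or 8 (0.117).

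**Figure D4:**
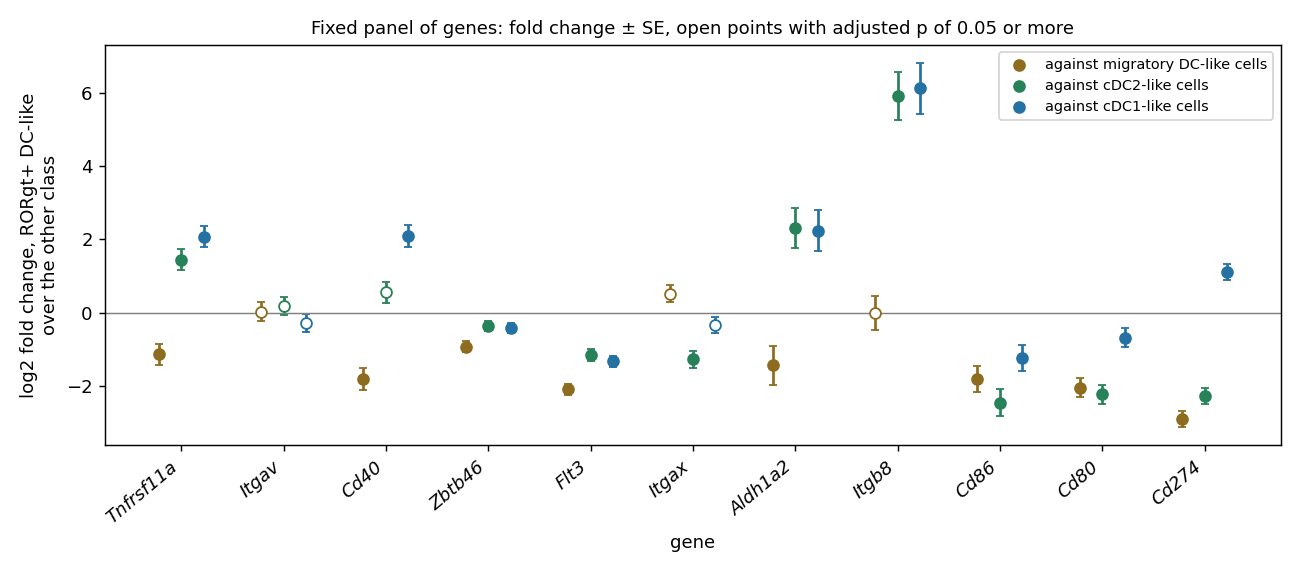
Log2 fold changes of the 11 genes chosen beforehand (y axis, log2, RORgt+ DC-like over the other class) in each of the 3 contrasts; points are fitted values with SE bars, open where the adjusted p is 0.05 or more. Cd274 lies at -2.90 against migratory DC-like, -2.28 against cDC2-like and 1.11 against cDC1-like cells.

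The second contrast set RORgt+ DC-like cells against cDC2-like cells, the main classical DC subset of this sort. RORgt+ DC-like cells had less RNA of genes of MHC class II presentation: 12 of 15 fell and 0 rose, with H2-Ob at -2.78 ± 0.23 log2 and the peptide-loading gene H2-DMa at -1.43 ± 0.18. Peptide loading itself was not measured. As a list, MHC class II presentation did not pass with an estimated correlation (adjusted p = 0.305) or with cluster 28 alone (adjusted p = 0.0798). They also had less Cd86 (-2.46 ± 0.37), Cd274 (-2.28 ± 0.22) and Cd80 (-2.23 ± 0.27), and less of the core DC genes, of which 14 of 18 fell and 3 rose, although the list core dendritic cell identity did not pass with an estimated correlation (adjusted p = 0.0727). They had more Itgb8 (5.91 ± 0.66), Aldh1a2 (2.31 ± 0.55), Ltb (2.37 ± 0.42) and Ido2, which encodes a tryptophan-degrading enzyme (4.66 ± 0.58). Of these, Itgb8 and Aldh1a2 did not pass with cluster 26 alone (adjusted p = 0.871 and 0.587). In the fit of all pairs, each of these genes had the same sign in 5 of 5 pairs.

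Of the genes counted, 3654 passed the edgeR test against cDC2-like cells, 1536 higher and 2118 lower (42.0% higher); with DESeq2 and its size factors 52.4% of the calls were higher. Of the fixed lists, 4 were lower and 0 higher. With cluster 28 alone, 3 of the 4 lists that passed were higher and 1 lower, and with hashtags 2, 4 and 5 only, 2 of 5 were higher and 3 lower. MHC class I presentation and the NF-kB and TNF receptor family were higher in both of these settings. MHC class II presentation had an adjusted p of 0.000688 (adjusted p = 0.305 with an estimated correlation, 12 called when adjusted over the list alone). Among costimulatory and coinhibitory ligands 9 of 16 fell and 1 rose (adjusted p = 0.00468, adjusted p = 0.237 with an estimated correlation, 10 called when adjusted over the list alone), with Vsir, which encodes VISTA, at -3.34 ± 0.31. Core dendritic cell identity had an adjusted p of 0.0109 (adjusted p = 0.0727 with an estimated correlation, 17 called when adjusted over the list alone), with Kmo at -2.79 ± 0.36 and the transcription factor gene Bcl11a at -2.37 ± 0.31. Of 15 Toll-like receptors and adaptors 7 fell and 1 rose (adjusted p = 0.0119, adjusted p = 0.144 with an estimated correlation, 9 called when adjusted over the list alone), the 1 that rose being Tlr12 (5.84 ± 0.30). With cluster 28 alone, costimulatory and coinhibitory ligands (adjusted p = 0.222) and core dendritic cell identity (0.0850) did not pass. The former also did not with hashtags 2, 4 and 5 only (0.108), the latter with hashtags 6 and 9 only (0.0821), and Toll-like receptors and adaptors with cluster 26 alone (0.0806).

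The remaining lists did not pass against cDC2-like cells. In TGF-beta activation and signalling 7 of 13 fell and 2 rose, with Smad7 at -2.04 ± 0.18 and Tgfbr1 at -1.82 ± 0.37 (adjusted p = 0.113, 9 called when adjusted over the list alone). In retinoic acid metabolism and signalling 5 of 13 rose and 2 fell (adjusted p = 0.129, 7 called when adjusted over the list alone), and Rarb was 33.8-fold lower (6.06 to 1337) from 1 UMI. Of the chemokines 5 of 12 fell (adjusted p = 0.113, 5 called when adjusted over the list alone), with Ccl4 at -3.13 ± 0.62, and of the cytokines 6 of 13 fell and 2 rose (adjusted p = 0.113, 8 called when adjusted over the list alone), with Il18 at -3.90 ± 0.47. MHC class I presentation was called in 1 gene each way and in 2 when adjusted over the list alone (adjusted p = 0.129). The NF-kB and TNF receptor family had 5 of 19 higher, 3 lower and 8 called when adjusted over the list alone (adjusted p = 0.169). Phagocytosis and scavenging had 4 of 11 lower, 2 higher and 6 called when adjusted over the list alone (adjusted p = 0.495), with Stab1 at 4.41 ± 0.34 and the inhibitory Fc receptor gene Fcgr2b at -3.73 ± 0.60. Cholesterol and sterol synthesis had 4 of 15 lower, 1 higher and 5 called when adjusted over the list alone (adjusted p = 0.770). The tolerance-linked enzymes and receptors had 3 of 10 higher, 4 lower and 9 called when adjusted over the list alone (adjusted p = 0.546), and here the list's mean and median were above 0 while fry pointed down.

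Among the chosen genes, Tnfrsf11a was higher than in cDC2-like cells (log2 fold change 1.44 ± 0.29, edgeR adjusted p = 0.00061) and Flt3 (-1.15 ± 0.16, adjusted p = 1.05e-05), Itgax, which encodes CD11c (-1.28 ± 0.23, adjusted p = 0.000172), and Zbtb46 (-0.38 ± 0.14, adjusted p = 0.0373) were lower, each in 5 of 5 pairs. Cd40 (0.55 ± 0.29, adjusted p = 0.152, 4 of 5 pairs higher) and Itgav (0.17, adjusted p = 0.617, 4 of 5 pairs higher) did not pass. Tnfrsf11a differed by 1.87, 2.12, 2.45, 0.57 and 0.02 log2 in hashtags 2, 4, 5, 6 and 9 and did not pass with hashtags 6 and 9 only (0.47, adjusted p = 0.132). Itgb8 differed by 5.61, 7.28, 8.25, 1.77 and 0.68 log2 in hashtags 2, 4, 5, 6 and 9 (adjusted p = 8.57e-07 over all pairs), and Aldh1a2 by 3.14, 2.56, 2.67, 1.38 and 0.92 log2 (adjusted p = 0.00263). Among other genes, Scube1 (8.77 ± 0.61, adjusted p = 1.15e-09), Prr29 (8.72 ± 0.38, adjusted p = 1.77e-12) and Foxs1 (8.14 ± 0.53, adjusted p = 3.65e-08) were higher in 5 of 5 pairs, and Plet1os was at least 12.3-fold and Acss1 at least 7.30-fold lower. With cluster 26 alone the differences of Itgb8 (0.52, adjusted p = 0.871), Aldh1a2 (0.63, adjusted p = 0.587) and Tnfrsf11a (0.09, adjusted p = 0.873) no longer passed, and with hashtags 6 and 9 alone Itgb8 did not (1.86, adjusted p = 0.185). The call for Zbtb46 was lost without hashtag 2 (adjusted p = 0.0510), 4 (0.118), 5 (0.158) or 6 (0.0576) and with other size factors (0.110).

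The third contrast set RORgt+ DC-like cells against cDC1-like cells, the subset specialised in cross-presentation. The NF-kB and TNF receptor family was higher: 15 of 19 genes rose and 0 fell, with Ltb at 5.09 ± 0.46 log2, Tnfrsf1b at 2.46 ± 0.46 and the NF-kB-inducing kinase gene Map3k14 at 2.19 ± 0.26. With an estimated correlation this list did not pass (adjusted p = 0.116), and neither did the next (adjusted p = 0.194). Of 10 tolerance-linked enzymes and receptors 7 rose and 1 fell, with Adora2a at 3.44 ± 0.40 and Axl at 2.31 ± 0.55. Cd40 (2.09 ± 0.29), Tnfrsf11a (2.07 ± 0.29), Itgb8 (6.11 ± 0.70), Aldh1a2 (2.24 ± 0.57) and the IL-23 subunit gene Il23a (5.62 ± 0.71) were higher, although Itgb8, Aldh1a2 and Tnfrsf11a did not pass with cluster 26 alone (adjusted p = 0.857, 0.586 and 0.0981). Tlr3 (-6.07 ± 0.39), Tlr11 (-4.79 ± 0.44), Btla (-5.48 ± 0.52) and the scavenger receptor gene Cd36 (-4.02 ± 0.45) were lower. Each of these had the same sign in 5 of 5 pairs. The level of Il23a was not particular to RORgt+ DC-like cells. Its median was 12.2 CPM in their libraries (2.47 to 83.1) and 14.1 CPM in cDC2-like libraries (0.867 to 42.4).

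Of the genes counted, 3945 passed the edgeR test against cDC1-like cells, 1679 higher and 2266 lower (42.6% higher); with DESeq2 and its size factors 54.2% of the calls were higher, and the median of all genes shifted by 0.116 log2 between scalings. The NF-kB and TNF receptor family had a list adjusted p of 2.52e-10 (adjusted p = 0.116 with an estimated correlation, 15 called when adjusted over the list alone). The tolerance-linked enzymes and receptors had an adjusted p of 0.0101 (adjusted p = 0.194 with an estimated correlation, 8 called when adjusted over the list alone). Cholesterol and sterol synthesis was higher with 3 of 15 genes risen, Idi1 (2.59 ± 0.41), Hmgcs1 (1.22 ± 0.31) and Msmo1 (1.06 ± 0.31), and 3 called when adjusted over the list alone (adjusted p = 0.00446, adjusted p = 0.544 with an estimated correlation). With cluster 26 alone, tolerance-linked enzymes and receptors (adjusted p = 0.104) and cholesterol and sterol synthesis (0.431) did not pass, and with hashtags 6 and 9 only neither did (0.137 and 0.0624).

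The other lists did not pass against cDC1-like cells. Toll-like receptors and adaptors had 5 of 15 lower, 1 higher and 6 called when adjusted over the list alone (adjusted p = 0.0548). Core dendritic cell identity had 11 of 18 lower, 4 higher and 15 called when adjusted over the list alone (adjusted p = 0.151), with Mycl at -3.42 ± 0.29 and Nfil3 at 1.85 ± 0.25. MHC class II presentation had 7 of 15 lower, 3 higher and 10 called when adjusted over the list alone (adjusted p = 0.365), with H2-Ob at -2.59 ± 0.23. MHC class I presentation had 7 of 13 lower, 3 higher and 10 called when adjusted over the list alone (adjusted p = 0.223), with Pdia3 at -1.60 ± 0.16 and the peptide transporter gene Tap1 at -1.04 ± 0.17. Costimulatory and coinhibitory ligands had 4 of 16 higher, 6 lower and 12 called when adjusted over the list alone (adjusted p = 0.730), with Icosl at 2.63 ± 0.27; the median and camera pointed up, the mean and fry down. Retinoic acid metabolism and signalling had 6 of 13 higher, 3 lower and 9 called when adjusted over the list alone (adjusted p = 0.207). The cytokines had 2 of 13 higher, 4 lower and 6 called when adjusted over the list alone (adjusted p = 0.730). The chemokines had 2 of 12 higher, 3 lower and 8 called when adjusted over the list alone (adjusted p = 0.904), with a median above 0 and a mean and test below it. TGF-beta activation and signalling had 2 of 13 higher, 3 lower and 5 called when adjusted over the list alone (adjusted p = 0.904), with a mean above 0 and a median and test below it. Phagocytosis and scavenging had 4 of 11 higher, 3 lower and 7 called when adjusted over the list alone (adjusted p = 0.503).

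Among the chosen genes, Cd274 was higher than in cDC1-like cells (log2 fold change 1.11 ± 0.22, edgeR adjusted p = 0.000358), while Flt3 (-1.33 ± 0.16, adjusted p = 1.21e-06), Cd86 (-1.24 ± 0.35, adjusted p = 0.0078), Cd80 (-0.68 ± 0.26, adjusted p = 0.046) and Zbtb46 (-0.41 ± 0.14, adjusted p = 0.022) were lower, each in 5 of 5 pairs. Itgav (-0.28, adjusted p = 0.382) and Itgax (-0.34, adjusted p = 0.252) did not pass, with 3 of 5 pairs lower for each. Itgb8 differed by 6.35, 5.32, 9.74, 2.70 and 0.51 log2 in hashtags 2, 4, 5, 6 and 9 (adjusted p = 6.89e-07 over all pairs), Il23a by 4.28, 1.20, 1.17, 6.60 and 5.93 log2, and Aldh1a2 by 5.65, 3.61, 4.12, 0.60 and 0.07 log2 (adjusted p = 0.00376). Among other genes, Foxs1 was at least 391.2-fold, Krt28 at least 219.7-fold and Lingo4 1254-fold higher (218.5 to 50150, from 1 UMI in cDC1-like cells), and Fgd6 was at least 46.3-fold and the chemokine receptor gene Cxcr3 at least 17.8-fold lower. With cluster 26 alone Itgb8 (0.60, adjusted p = 0.857), Aldh1a2 (0.64, adjusted p = 0.586) and Tnfrsf11a (0.70, adjusted p = 0.0981) no longer passed, and without the hashtag block Cd274 (0.90, adjusted p = 0.224) and Cd86 (-1.31, adjusted p = 0.235) did not. Leaving out hashtag 4 or 5 ended the calls for Cd80 (adjusted p = 0.177 and 0.0718) and Zbtb46 (0.106 and 0.121), and hashtag 2 or 6 that for Cd80 (0.174 and 0.101).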

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

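Every value in this part was found by screening rules applied after the contrasts had been run, and no explanation was tested for any of them. Of 184 sets of 5 or 6 hashtag values, 8 held a value that stood apart from the others, and chance alone gives about 1 in 20 such sets.

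The difference of Csf2rb between RORgt+ DC-like and migratory DC-like cells was -3.10 log2 in hashtag 6, against -2.20 to -1.89 in the other hashtags. Slamf1 was at -7.83 log2 against migratory DC-like cells in hashtag 6, with -6.74 to -6.31 elsewhere, and Il12b was at -3.57 log2 in hashtag 2, with -8.12 to -7.37 elsewhere. Against cDC1-like cells, Cxcl9 was at -9.41 log2 in hashtag 5 (others -4.60 to -3.83) and Vsir at -6.37 log2 in hashtag 2 (others -3.36 to -2.14). Rarb was at -5.00 log2 against cDC1-like cells in hashtag 6 (others -3.67 to -3.25), and Ido2 at 2.31 log2 in hashtag 9 (others 4.50 to 5.34). The reporter sequence hCD2 was at 5.06 log2 against cDC2-like cells in hashtag 2, with 6.58 to 7.08 in the other hashtags. All of these kept the direction of their contrast. Apart from Csf2rb, they rest on few counts: RORgt+ DC-like libraries held 0 UMIs of Slamf1, 1 of Rarb, 7 of Vsir, 8 of Il12b, 15 of Cxcl9 and 22 of Ido2 in all. The libraries set apart for Slamf1, Cxcl9, Vsir and Rarb held 0, as did most cDC1-like libraries for Ido2. Such differences are set by the prior count and the depth of the libraries, so their sizes are not measured folds and the gaps to the other hashtags have no reading of their own.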

How the results depend on the processing

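The settings that use 1 cluster alone, count cluster 13 or its sub-cluster of 66 cells, count cluster 1 as cDC2-like, remove cells among multiplets, or use only part of the hashtags were chosen after the data had been seen; the others were planned. Under all settings together, 76 of 81 counts of called genes stayed within 1.5 times their main value. So did 72 of 78 counts of called lists. Of 4755 values of named genes, 4522 kept their side of the threshold and, where called, their direction, with 203 losing and 17 gaining a call. A named gene that a setting did not test gave no value and was not counted as a lost call. Of the 179 named-gene results, thinning to equal UMI totals gave only 123 kept, 6 losing and 2 gaining a call. A value without a call in either fit was counted as kept whatever its sign. By the same rule 933 of 1014 values of list tests were kept, with 31 losing and 49 gaining a call. DESeq2 gave no list values. The 3 RORgt+ DC-like cells of hashtag 8 and totals of 282582 to 614904 UMIs per RORgt+ DC-like library limit what rare transcripts can show.

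Leaving out each hashtag in turn gave 2707 to 3498 genes against migratory DC-like, 2893 to 3513 against cDC2-like and 3193 to 3809 against cDC1-like cells, and Gm38411 log2 fold changes of 8.58 to 11.37, 8.87 to 10.49 and 11.34 to 11.60. These folds rest on 1, 9 and 0 UMIs in the other class and depend on the prior count, so the last are not measured sizes. Called lists numbered 4 to 7, 4 to 6 and 3 to 4. Without the hashtag block, that is with no replicate block in place of the pairing, 2506, 2640 and 2868 genes were called. Thinning to equal UMI totals gave 2050, 1956 and 2072 genes, out of 5856 counted, since fewer genes passed the count filter. Requiring at least 30 cells, which leaves 3 pairs, gave 2224 genes against migratory DC-like cells, and cluster 28 alone gave 1241 genes and 2 lists. Against cDC2-like cells, 2 lists were called with cluster 13 counted and 7 with hashtags 6 and 9 only. Against cDC1-like cells, 5 lists were called without the low-count filter, and 1 with cluster 26 alone and with hashtags 6 and 9 only. Apart from the thinning, the cause was not tested.

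Of 168 class shares per hashtag, 147 stayed within their interval; 9 of the others moved at the limit of 5% mitochondrial counts. The median share of cDC2-like cells rose to 57.6% at resolution 0.5. Thinned to 1000 UMIs, Gm38411 was seen in 8.22% of RORgt+ DC-like, 3.39% of ILC3-like and 0 of 7818 cDC2-like cells, which allows up to 0.038%; unthinned, in 47.9% of RORgt+ DC-like and 39.0% of ILC3-like cells. These shares depend on depth. The RORgt+ DC-like and ILC3-like shares, close to each other at 2000 UMIs, were further apart at 1000 UMIs, where few ILC3-like cells held a UMI.

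Some values changed sign. With cluster 28 alone against migratory DC-like cells, the mean of cholesterol and sterol synthesis was 0.014 (adjusted p = 0.422), Itgax was at -1.36 (adjusted p = 0.0200) and Itgb8 at 1.46 (adjusted p = 0.0350). With cluster 13 counted, Rarb was at 1.30 against migratory DC-like, 0.89 against cDC2-like and 1.56 against cDC1-like cells, Btla at 0.33 against cDC2-like and Cd80 at 1.05 against cDC1-like cells. With its sub-cluster of 66 cells counted, Rarb was at 0.73, 0.35 and 1.02, and Cd80 at 0.70 against cDC1-like cells. With hashtags 6 and 9 only, Itgav was at 0.50 and Itgax at 0.48 against cDC1-like cells. The cause was not tested.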

Other observations

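The comparisons between clusters of the RORgt+ DC-like class, the tdTomato gene test and its splits, the test of free tdTomato RNA, the test of doublets by Prdm16 and the test of RORgt+ DC-like depth were chosen after the values they concern had been seen; the other tests were not.

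Within the RORgt+ DC-like class, genes that had been kept out of the clustering differed between its parts in the same hashtag. In hashtags 2, 4 and 5, the cluster with Aire among its leading genes, numbered 28, held Itgb8 at 151.6, 483.8 and 611.4 CPM, while the one numbered 26 held it at 11.8, 0 and 7.27 CPM, from 2 UMIs in all. Aldh1a2 was at 156.7, 129.0 and 162.2 CPM in the former and 11.8, 0 and 0 CPM in the latter. Gm38411 went the other way, with 45.5, 58.1 and 29.1 CPM in the former and 106.2, 132.7 and 152.7 CPM in the latter. These are values of 9 to 23 cells per hashtag with no test. Itgb8 was also high in a migratory DC-like cluster of 335 cells led by Mab21l3, at 295.8, 390.8 and 533.7 CPM.

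Other clusters stood out by their leading genes. A cDC2-like cluster of 70 cells was led by the interferon-induced genes Rsad2, Ifit3 and Ifit1, and an unnamed cluster of 2002 cells by Tnfsf9, Batf, Ccr7 and Il1b. A cluster of 21 cells was led by Ctrb1, Reg1 and other pancreatic enzyme genes. Among the hashtags, the median mitochondrial share before filtering was 6.07%, 6.09%, 6.66%, 1.60%, 1.64% and 1.52% in hashtags 2, 4, 5, 6, 8 and 9, and 34.3%, 34.3%, 35.2%, 9.87%, 9.98% and 6.32% of their cells exceeded the limit of 10%.

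Some cDC2-like cells held many tdTomato UMIs: 67 of 1517, 132 of 1458 and 290 of 2839 cells had at least 10 in hashtags 6, 8 and 9 (4.42%, 9.05% and 10.2%), and 0 did in hashtags 2, 4 and 5. Such cells were not confined to that class: in hashtags 6, 8 and 9 the unnamed cluster 1 had them in 43 of 632, 40 of 455 and 91 of 909 cells, and the migratory DC-like class in 1 of 55, 2 of 16 and 3 of 54. Counts were not thinned, and cells of hashtags 2, 4 and 5 were shallower. As a share of UMIs, cDC2-like cells held tdTomato at 31.2, 37.2 and 44.3 CPM there, against 97.9, 159.5 and 176.5 CPM in hashtags 6, 8 and 9. Free RNA in the droplets is argued against, because cDC1-like cells, which are deeper, reached 0.735%, 2.61% and 1.72%, and the intervals of both classes stayed at least 1.62 percentage points apart. Doublets with RORgt+ DC-like cells are argued against as well, because 1.84% of these cells (9 of 489, 0.971% to 3.46%) held a Prdm16 UMI, against 50 of 51 RORgt+ DC-like cells of hashtags 6, 8 and 9 and 1.38% of cDC2-like cells without tdTomato. The labels name no tdTomato allele and no tissue per hashtag, so past or present activity of a Cre allele in part of these cells may account for the pattern and stays untested, as does the tissue.

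These cells were then compared with cDC2-like cells without a tdTomato UMI, matched on cluster and total UMIs within each hashtag. There were 67, 132 and 290 cells per side, and the hashtag was a block. The comparison therefore leaves out differences between cDC2-like clusters. Of 8381 genes tested, edgeR called 52, 18 higher and 34 lower in the tdTomato cells, of which 46 had the same sign in all 3 hashtags. The genes named here were picked after their values were seen. Map4 (log2 fold change 1.46 ± 0.12, edgeR adjusted p = 1.1e-12), Ptpn3 (1.78 ± 0.21, adjusted p = 1.28e-07), Gt(ROSA)26Sor (1.20 ± 0.24, adjusted p = 0.00313) and Rora (0.99 ± 0.20, adjusted p = 0.00313) were higher in 3 of 3 hashtags. Dab2 (-1.73 ± 0.28, adjusted p = 6.82e-05), Btla (-1.44 ± 0.21, adjusted p = 1.18e-05) and Igf1r (-0.91 ± 0.12, adjusted p = 1.73e-06) were lower in 3 of 3 hashtags. The haemoglobin genes Hba-a1 (-7.00) and Hbb-bs (-6.02) were also called, but 1731 of 1744 Hba-a1 UMIs of hashtag 8 lay in 1 cell and 1710 of 2322 of hashtag 9 in 1 cell. Other size factors called 45 genes, DESeq2 12 and a fit without the block 8, and leaving out hashtag 6, 8 or 9 gave 23, 49 and 54. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split gave 52 genes and the highest of the others 3.

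RORgt+ DC-like cells held more UMIs than cDC2-like cells in hashtags 6 and 9 (medians of 23146 against 13064 and 24564 against 13228). Doublets within a hashtag are argued against as the main source, because hashtag multiplets made up 23.3% and 26.7% of their nearest neighbours, against 16.7% for cDC2-like cells and 80.0% that the sizes of the hashtags give for a cluster made of doublets. No biological explanation was tested.

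Other splits of the summed libraries of each contrast were fitted to count the genes that each calls. The 16 splits that part every pair of a hashtag, as the contrasts do, are too few for a share under 0.05. In each contrast 1 of 16, the real one, gave as many genes: 3541, 3654 and 3945 against migratory DC-like, cDC2-like and cDC1-like cells, and the highest of the others 256, 198 and 425. Splits drawn from all 126 possible ones, most of which leave some pairs together, reached 1752, 717 and 667 genes apart from the real one. The classes were clusters of the same expression values, so the real split was bound to call many genes, and its lead is no evidence of its own.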
